A study of Mus musculus with 6 samples.

How the data were processed

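RNA was measured by sequencing in mouse embryonic stem cells of C57BL/6J origin that carry floxed alleles of Mll1 (Kmt2a) and a tamoxifen-inducible Cre. The labels list 6 libraries in 3 groups of 2, named as biological duplicates: untreated cells, cells given 1 µM of 1α,25-dihydroxyvitamin D3 (VD3) for 5 days, and cells given the same VD3 together with 100 µM MM-401, an inhibitor of the MLL1 histone methyltransferase, for 5 days. No group received MM-401 alone, so an interaction of both agents could not be estimated. The cells grew with leukemia inhibitory factor and 15% fetal calf serum or 20% serum replacement on fibroblast feeder cells. The labels list both media for every library and give no time for the untreated cells. A difference in either between groups could not be told apart from the treatment. Libraries were made with the TruSeq protocol, per the labels' protocols.

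Per the submitters' processing notes, the authors used TopHat2 2.1.1, SAMtools 1.5 and Cufflinks 2.2.1 with the mouse build mm10; the order and the settings of these steps are not given in the sources used here. The deposited tables give FPKM for 62490 assembled loci and, per the file headers, a lower and an upper confidence bound for each FPKM, whose level is not given. A companion table that the authors deposited holds the estimated count of each locus, which need not be a whole number, and the variance of that count. Both tables hold 1 pooled column per group and not 1 per library. The column of the VD3 group carries its name; the untreated column and the VD3 plus MM-401 column were matched through the part of the name that only their group's titles share, while the rest of both names is not explained by the labels. A different meaning of those names would change every comparison with these columns. Over the 9960 loci with a count above 500 in every pool, the ratio of FPKM to count had a median of 1 between either treated pool and the untreated pool, with 5th and 95th percentiles of 0.833 and 1.24 for VD3 and 0.741 and 1.43 for VD3 plus MM-401. The authors' upper bound lay 2.31, 2.28 and 2.34 standard deviations of the count above the FPKM, as a median over these loci, in the untreated, VD3 and VD3 plus MM-401 pools.

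The total estimated count was 62284598 in the untreated pool, 73636342 in the VD3 pool and 73499639 in the VD3 plus MM-401 pool. The standard deviation that the authors' variance implies was 17.5%, 17.5% and 18.3% of the count for the median locus above 500 counts. The 14 loci without a valid status in every pool were left out. They include both loci that carry the mitochondrially encoded genes, which are listed at 0, so the mitochondrial list has no values. Of the loci, 11771 carry no gene name. Values, bounds and counts of loci that share a gene name were summed, which gave 49377 names, 1113 of them with more than 1 locus. A locus that names exactly 1 protein-coding gene was assigned to it, and a locus that names several keeps all names. Of the 51398 distinct single names in the tables, 47287 are in GENCODE vM21 (GRCm38, the sequence of mm10), and 99.9% of the loci with a single such name overlap that gene. In the tables, 22 names have the form of spreadsheet dates. Coordinates are from GENCODE vM21, counted from 1. The kit and the counting are not stated to use strand, so overlapping and antisense genes cannot be told apart.

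The design fixed before the data were examined foresaw a count test across libraries, with the plan that pooled columns would receive no test. The tables allowed only that fallback, so no p-value is given. Each difference is the log2 ratio of FPKM + 1, which understates the difference of low genes. Genes with at least 5 FPKM in the higher pool entered a comparison. A gene was counted as higher or lower where the difference was at least 1 on the log2 scale (2-fold) and the authors' intervals did not overlap, a criterion set after the tables were opened. The intervals describe the authors' model of each pool, and no spread between libraries stands behind a count of genes. The median gene differed from untreated by more than 0.1 on the log2 scale in both treated pools. Some single genes are therefore also given a difference relative to the median gene of the comparison, written as a relative log2 difference. FPKM values are printed as deposited. Neither they nor the main counts of higher and lower genes are corrected for the shift of the median gene. For each list of genes fixed before the data were examined, the median difference of its members with a mean of at least 1 FPKM was placed as a percentile among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Lists with at least 5 such members were placed, and percentiles above 97.5 or below 2.5 were counted as outside the random lists. These percentiles describe the pools and not the conditions. Where random lists were also matched on GC content and length, they came from protein-coding genes only, with fewer and wider bins of expression. A percentile that moves under this matching may thus move through the coarser expression bins too. Genes of different length share a bin there, so part of a length trend can remain.

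The genes named in the text follow a rule fixed before the data were examined: the 10 largest differences in each direction among genes of at least 5 FPKM, 18 genes fixed by name, and up to 4 members of each list with the largest difference. Since the first part of the rule mostly named small RNAs with few counts, a rule chosen after seeing the data added the 10 protein-coding genes per direction with the largest difference among those with at least 100 estimated counts in the higher pool, intervals apart and a 2-fold difference on the count scale as well. Gata3, among the fixed genes, shares its locus with another gene and is not reported. GC content and length were those of the longest transcript in GENCODE vM21. An adjusted difference, given only for protein-coding genes, is the difference minus the median of such genes in the same of 8 GC bins and 8 length bins within each. The chance relation of comparisons that share a pool, and the chance overlap of their genes, were taken from 100 simulations of unchanged pools drawn with the authors' variances. The simulations held no trend with GC content or length.

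The calling step was tested on simulated pools with 200 genes changed 4-fold. It recovered 65.5% of them among 10911 genes for VD3 against untreated, 61% among 10966 for VD3 plus MM-401 against untreated and 64% among 10717 for VD3 plus MM-401 against VD3. Of the unchanged genes, 1.13%, 1.23% and 1.34% were called (121, 132 and 141 genes). In these simulations and those of the overlap, each interval was scaled with its drawn value. A gene drawn very low thus had almost no interval and was easily called. The simulated counts therefore cannot set how many calls the authors' variance alone gives. Of 40 simulated lists of 20 genes shifted by 0.5 on the log2 scale, 39, 36 and 40 were placed above the random lists, and of 40 unshifted lists 1, 2 and 2 lay outside them. The unshifted lists were drawn at random from the measured genes, so the share of them outside is set by the limits. It does not give the rate for lists whose members vary together. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the pseudocount, the expression minimum, the scaling, the count table in place of FPKM, the intervals, the summing of loci, and adjustment for GC content and length.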

Results

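The data are gene expression values of mouse embryonic stem cells, pluripotent cells derived from the blastocyst, in 3 groups: untreated, treated with VD3, the hormonally active form of vitamin D, and treated with VD3 together with MM-401, which inhibits the MLL1 histone methyltransferase. The 2 libraries of each group were pooled in the deposited tables, so no difference below has a replicate check. The pools held 62284598 (untreated), 73636342 (VD3) and 73499639 (VD3 plus MM-401) estimated counts. Unnamed loci took 0.36%, 0.346% and 0.408% of them, and the 10 largest loci took 3%, 3.59% and 3.37%.

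The pools expressed pluripotency genes at high levels. Pou5f1 (chromosome 17, 35506018 to 35510772), which encodes the transcription factor OCT4, stood at 1114 FPKM in untreated cells (authors' interval 591 to 1638), 2053 with VD3 and 1832 with VD3 plus MM-401. Sox2 was at 156.5, 163 and 195 FPKM, Esrrb at 109, 150 and 117, Klf4 at 76.2, 62.6 and 63.0, and Zfp42 at 26.4, 26.7 and 30.9, in the same order of pools. Nanog (chromosome 6, 122707489 to 122714633) summed to 117, 141 and 156 FPKM over 2 loci. The authors' intervals of each of these genes overlapped between the pools. These FPKM values include the shift of the median gene. With VD3 against untreated, the relative log2 differences were 0.52 for Pou5f1, 0.10 for Esrrb and -0.09 for Nanog. They were -0.31 for Sox2, -0.35 for Zfp42 and -0.64 for Klf4. Kmt2a, the gene of MLL1, was at 14.9, 11.6 and 17.0 FPKM, the last with an interval of 0 to 41.35. Its estimated counts were 9515, 7054.7 and 7749.6, so by count it was lower with VD3 plus MM-401 than in untreated cells. Vdr, the vitamin D receptor, was low, at 0.556, 0.701 and 0.370 FPKM, and Cyp24a1, the vitamin D catabolic enzyme and a classical target of the receptor, was at 0.0662, 0.130 and 0.0719 FPKM. Hoxa9 and Zscan4d were below 1 FPKM in every pool, as were Fgf5 and Sox17. Otx2 was at 8.70, 5.88 and 8.88 FPKM, Cdx2 at 1.42, 3.26 and 2.202, Gata6 at 1.01, 0.588 and 0.344, and Dppa3 at 17.8, 16.0 and 26.0.

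**Figure D1:**
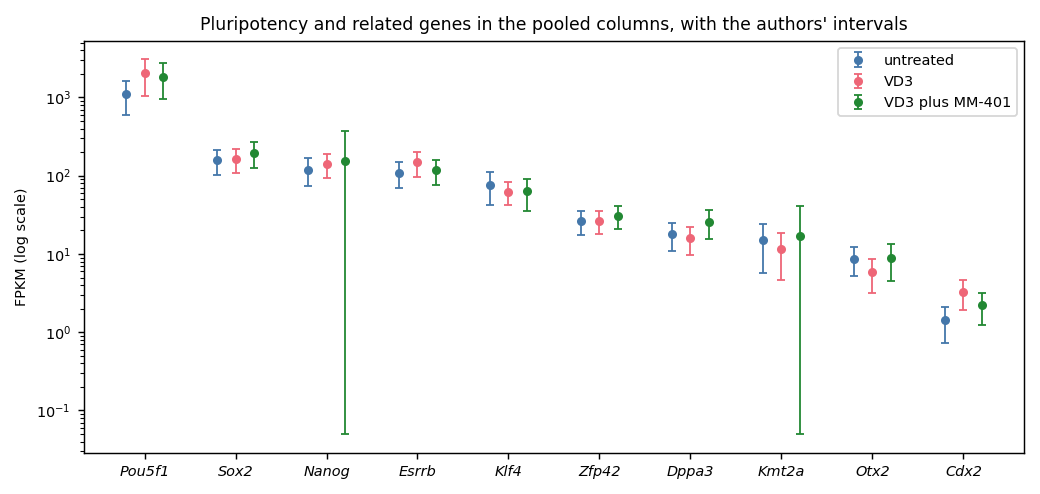
FPKM of 10 genes on a log axis in the untreated, VD3 and VD3 plus MM-401 pools. Points are the authors' pooled values and bars their confidence bounds, and a bound of 0 (Nanog and Kmt2a with VD3 plus MM-401) is drawn at the foot of the axis. Pou5f1 lies between 1114 and 2053 FPKM, and the bars of the 3 pools overlap for each of the 10 genes.

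The comparison of VD3 with untreated cells asks which transcripts differ after 5 days with the hormone. Targets of Wnt-beta-catenin and FGF-ERK signalling stood high in the VD3 pool as lists, cholesterol biosynthesis genes stood low, and more single genes were lower than higher. Vim, the intermediate filament vimentin, was at 50.4 FPKM in untreated cells (interval 26.6 to 74.2) and 159 with VD3 (88.5 to 230). Id1, a target of BMP signalling, was at 45.5 and 119 FPKM, Nefl, a neurofilament subunit, at 5.94 and 19.3, and Bmp4, which encodes a BMP ligand, at 10.8 and 28.9. Atrx, a chromatin remodeller, was at 162 FPKM in untreated cells (44.8 to 279) and 9.65 with VD3 (2.95 to 16.3). Rif1, a telomere and replication timing factor, was at 73.4 and 10.4 FPKM, and Thoc2, part of an mRNA export complex, at 41.5 and 5.43.

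Of 10911 genes, 101 were higher and 460 lower with VD3 by the criterion of a 2-fold difference with intervals apart. Among unchanged genes of simulated pools the same criterion called 66 higher and 55 lower. Intervals there shrank with the drawn value, so how many of the 101 and 460 genes are chance calls is not known. Among protein-coding genes of at least 100 counts, 52 were higher and 342 lower, against 23 and 16 in the simulation. The median gene was 0.36 higher on the log2 scale with VD3. With values centred on it, 46 genes were higher and 707 lower. Of the protein-coding genes, 57 were higher and 343 lower. Genes that the added rule named as higher included Rps21, at 163 and 566 FPKM (relative log2 difference 1.43), Pla2g7 at 6.65 and 20.3 (1.11), Fkbp6 at 6.65 and 19.7 (1.08), Gast at 4.54 and 14.6 (1.13), Synpo2l at 3.67 and 11.2 (1.02) and Apobec2 at 3.63 and 10.9 (1.00). Gm21887 was listed at 0 in untreated cells and at 28.0 FPKM with VD3. Those named as lower were Atrx (relative log2 difference -4.30), Washc4 (-3.61), Ddx3y (-3.55), Trpm7 (-3.24), Trp53inp1 (-3.22), Thoc2 (-3.09), Rif1 (-3.07), Arhgap5 (-3.07), Hmgn5 (-3.06) and Mdm4 (-3.05). By the rule fixed beforehand, 9 of the 10 largest differences upward and 10 of 10 downward were small RNAs, such as Snord42a at 0 and 139 FPKM and Mir762 at 228 and 0 FPKM, and each had under 100 counts in both pools.

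The differences from untreated cells went with transcript composition. Across 8797 protein-coding genes, which are not independent replicates, the Spearman correlation of the VD3 difference with GC content was 0.567 and with transcript length -0.414. The bin of genes with the lowest GC content (median 40.7%) had a median difference of -0.91, and the bin with the highest (59.4%) one of 0.52. The 342 lower protein-coding genes with these values had a median GC content of 40.6% and a median length of 4847 bases, against 50.2% and 3055 bases for all. After adjustment for both properties, 113 of these 342 and 14 of the 57 higher genes still differed 2-fold in that direction. Adjusted differences were -2.66 for Atrx, -2.34 for Hmgn5, -1.45 for Thoc2, -1.43 for Rif1, 1.12 for Vim and 1.13 for Nefl. Id1 and Bmp4, with relative log2 differences of 1.00 and 0.98, were at 0.69 and 0.75 after adjustment, and the 2-fold difference of Bmp4 rests on its value of 1.34 before centring. For Kdm6a (14.0 and 5.64 FPKM), a histone demethylase gene on the MLL-family list, the adjusted difference was 0.15, and for Eda2r, a p53 target (10.05 and 3.815 FPKM), it was 0.01.

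**Figure D2:**
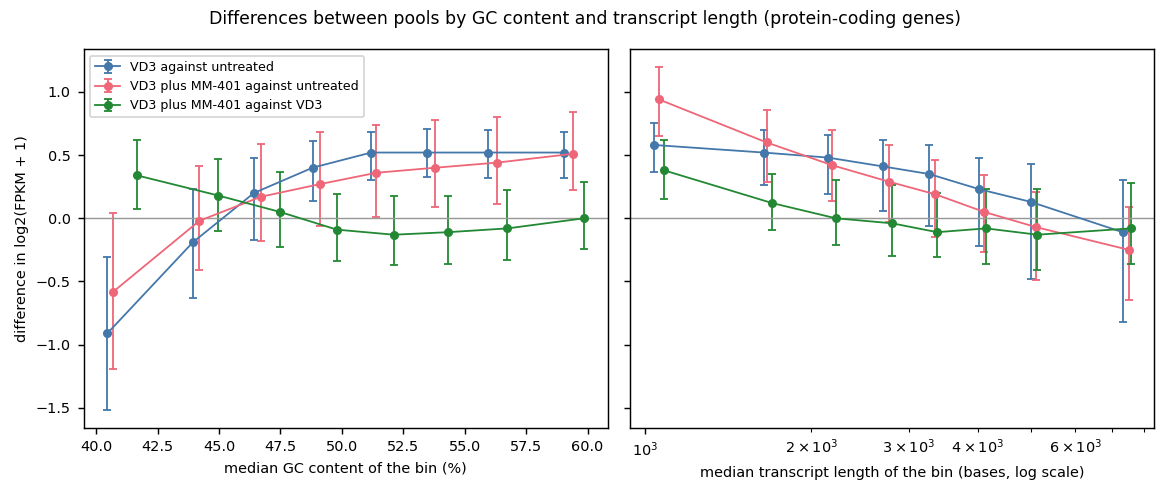
Median difference in log2(FPKM + 1) of protein-coding genes in 8 bins of GC content (percent, left) and of transcript length (bases, log axis, right) for the 3 comparisons. Bars span the lower to the upper quartile of genes and points of a bin are set slightly apart sideways. The VD3 minus untreated median runs from -0.91 in the lowest GC bin to 0.52 in the highest.

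Among the gene lists, targets of Wnt-beta-catenin signalling stood highest in VD3 against untreated. Their 11 measured members had a median difference of 0.82, at percentile 100 of the random lists, with 8 members above the median gene. Cdx1 was at 5.43 and 13.1 FPKM with intervals apart, Notum at 9.13 and 19.5, Lef1 at 6.53 and 14.1 and Myc at 43.6 and 87.0, the last 3 with overlapping intervals. The FPKM values of single genes include the shift of the median gene, 0.36 on the log2 scale. Feedback targets of FGF-ERK signalling were at percentile 99.5 with a median of 0.61 and 15 of 18 members above the median gene, among them Phlda1 at 9.29 and 19.9 FPKM, Ccnd1 at 71.1 and 133 and Egr1 at 3.77 and 7.54, all with overlapping intervals. Myc and Ccnd1 are on both lists. Ribosomal protein genes were at percentile 99.8 (median 0.65, 35 of 43 members above the median gene) and at 96.5, within the random lists, when these were also matched on GC content and length. The 91 measured genes with Rpl or Rps symbols, a set formed after seeing the data, were at 95.2, and at 55.5 with that matching. Of these, 3 were higher and 2 lower. The symbol pattern also admits some kinase genes, so the set may hold more than ribosomal protein genes. Cholesterol biosynthesis genes were at percentile 1.4, with a median of 0.01 and 4 of 20 members above the median gene; Insig1 was at 19.1 and 11.8 FPKM and Sc5d at 16.2 and 10.6, with overlapping intervals. With the matching on GC content and length, HOX cluster genes (0.4) and glycolysis and hypoxia (0.4) also lay below the random lists. For the 6 HOX cluster genes the median of the random lists rose from 0.15 to 0.35 with it, which may also come from the wider expression bins.

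Other lists lay within the random lists in this comparison. Naive pluripotency was at percentile 4.1 (median 0.30, 27 members), and at 0.7, below the random lists, by count with matching on GC content and length. On this list Lin28a stood at 117 and 257 FPKM with intervals apart and Tdh at 100 and 208. Formative and primed pluripotency was at 94.6, with Tcf15 at 167 and 364 FPKM and Foxd3 at 3.78 and 9.10, both with overlapping intervals, and at 99.5 among genes of at least 5 FPKM. Trophectoderm and trophoblast was at 93.4, mesoderm and primitive streak at 87.6, neuroectoderm at 72.7, primitive endoderm at 65.8 and germline genes at 47.2. Vitamin D receptor signalling, the pathway of the added hormone, was at percentile 23.1 with a median of 0.19. Of its 13 measured members none had intervals apart; Rxra was at 6.82 and 14.9 FPKM and Igfbp3 at 12.3 and 20.1. MLL-family complexes were at 45.2, HOX cluster genes at 13.9, TGF-beta, Nodal and BMP targets at 32.4, DNA methylation machinery at 51.6, imprinted genes at 14.0 and p53 targets at 23.4. Proliferation genes were at 14.8, glycolysis and hypoxia at 8.6, the integrated stress and unfolded protein response at 86.8 and interferon-stimulated genes at 20.2. Markers of other cells were placed as well. Fibroblast (feeder cell) markers were at 71.5, and at 98.0 among genes of at least 5 FPKM, with Vim and S100a6 (83.8 and 213 FPKM) the 2 of 18 measured members with intervals apart and higher, and macrophage and endothelial markers at 36.9. The 2-cell-like list and the replication-dependent histone list had 1 and 4 measured members and were not placed, and the mitochondrially encoded list had 0.

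**Figure D3:**
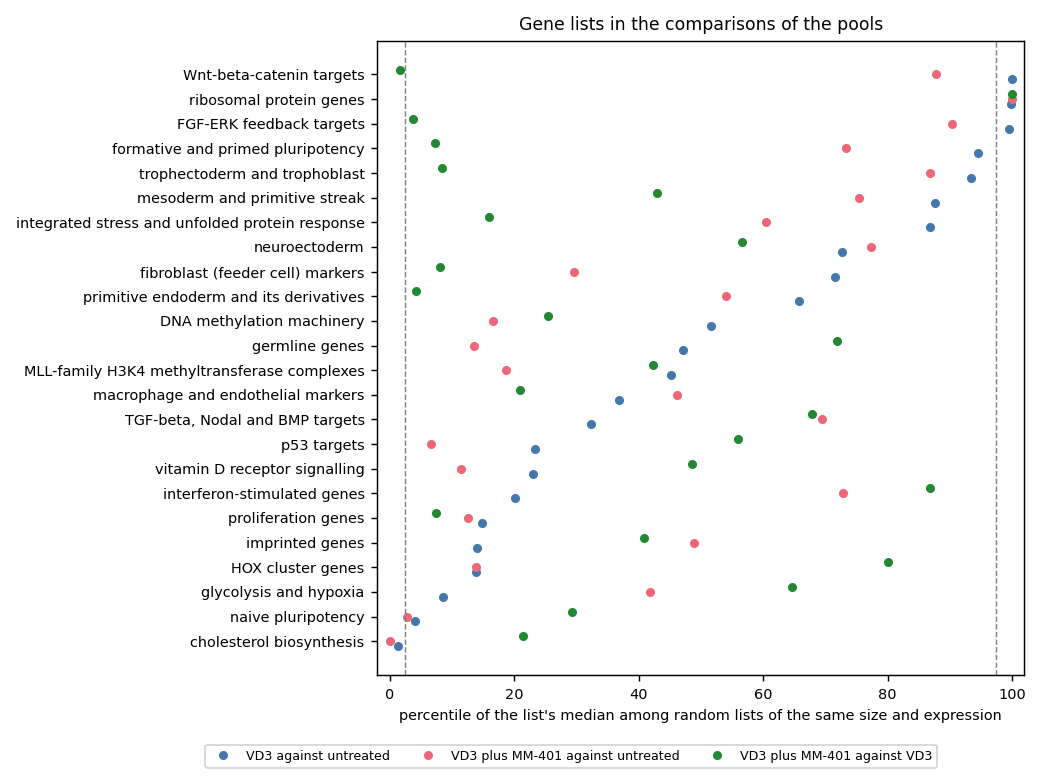
Percentile of each list's median difference among 10000 random lists of the same size and expression, for 24 lists in 3 comparisons of the pools. Dashed lines mark percentiles 2.5 and 97.5. Wnt-beta-catenin targets lie at 100 for VD3 against untreated and at 1.6 for VD3 plus MM-401 against VD3.

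The comparison of VD3 plus MM-401 with untreated cells asks what differs after both agents together, and does not separate MLL1 inhibition from VD3. Ribosomal protein genes were higher in this pool as a list, cholesterol biosynthesis genes were lower, and 253 genes that were lower with VD3 were lower here too. Rpl37, a ribosomal protein gene, was at 29.7 FPKM in untreated cells (19.2 to 40.2) and 153 with both agents (90.7 to 216). Rplp2 was at 389.5 and 1546 FPKM, Chchd7, a mitochondrial protein gene, at 33.5 and 141, and Mrps18c, of the mitochondrial ribosome, at 99.8 and 381. Atrx was at 162 and 14.8 FPKM, Arhgap5 at 36.9 and 3.16, and Kif20b, a mitotic kinesin, at 41.2 and 5.57.

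Of 10966 genes, 467 were higher and 294 lower, against 69 and 63 among unchanged genes of simulated pools. The median gene was 0.27 higher on the log2 scale, and with values centred on it 189 were higher and 403 lower, so the direction in which more genes differed depended on the scaling. Of the protein-coding genes 294 were higher and 189 lower. Arl5c (relative log2 difference 2.40), Rpl37 (2.06), Crct1 (2.02), Fam71e1 (2.01), Spink1 (1.92), Chchd7 (1.78), Rplp2 (1.72), Pemt (1.67), Pglyrp1 (1.67) and Mrps18c (1.65) were the higher genes that the added rule named. Atrx (-3.64), Ddx3y (-3.47), Arhgap5 (-3.46), Zfp518a (-3.26), Washc4 (-3.23), Phip (-3.05), Kif20b (-2.95), Kbtbd8 (-2.94), Gm38393 (-2.94) and Rif1 (-2.91) were the lower ones. By the rule fixed beforehand, 4 of the 10 largest differences upward and 10 of 10 downward were small RNAs, and Fgd6 was at 5.97 and 1264 FPKM while its estimated count was lower, at 912.5 and 594. Il3, an interleukin gene, was listed at 0 and 177 FPKM with 97.2 counts, under the minimum of the added rule. Sox2 had 27378 counts at 195 FPKM in the same pool, so the FPKM of Il3 is not a measure of comparable expression.

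Correlations across genes were 0.408 with GC content and -0.573 with length. The 294 higher protein-coding genes had a median length of 1154 bases against 3037 for all, and 52 of them were still 2-fold higher after adjustment, as were 96 of 188 lower genes. Ribosomal protein genes were at percentile 100 of the random lists with 41 of 43 members above the median gene, and 8 of them had intervals apart and were higher. They were also at 100 when random lists were matched on GC content and length. There the 91 genes of the Rpl and Rps symbol set were at 97.6, with 14 higher and 3 lower. The median difference was 0.94 in the bin of the shortest protein-coding genes (median 1060 bases) and 0.60 in the next (1660 bases). The matching uses wider length bins than these, so it cannot remove the whole length trend for short transcripts. Cholesterol biosynthesis genes were at 0.1 (median -0.29), and by count at 1.3 with a smaller median of -0.09. None of the 20 members had intervals apart. Dhcr7 was at 101.9 and 52.8 FPKM and Lss at 48.4 and 24.3, with log2 differences of -0.38 and -0.10 by count. With the matching on GC content and length, cholesterol biosynthesis was at 0.0 by FPKM. Naive pluripotency (2.1), vitamin D receptor signalling (1.5) and HOX cluster genes (0.5) then also lay below the random lists. By count with the matching, the 6 HOX cluster genes were at 11.9, within the random lists, and their median was 0.06 against -0.20 by FPKM. Naive pluripotency was at 2.7, Wnt-beta-catenin targets at 87.8, FGF-ERK feedback targets at 90.3, HOX cluster genes at 13.8, MLL-family complexes at 18.7 and vitamin D receptor signalling at 11.5. By count, MLL-family complexes, the family of the inhibitor's target, had a median difference of -0.11, against 0.15 by FPKM, and lay below the random lists at 0.8, and at 4.3 with the matching. Fibroblast markers were at 29.6. S100a6 was at 287 FPKM in this pool and Id1 at 128, with intervals apart from untreated, and Vim at 165 with overlapping intervals.

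The comparison of VD3 plus MM-401 with VD3 alone addresses the part that the inhibitor adds. Ribosomal protein genes were higher with the inhibitor as a list, and Wnt-beta-catenin targets, which stood high with VD3, were lower as a list, with 0 of 11 members having intervals apart. The Wnt-beta-catenin list lay within the random lists with matching on GC content and length (3.4) and among genes of at least 5 FPKM (8.3), and below them by count (0.1, and 0.0 with the matching). Both comparisons share the VD3 pool, so noise in it would put a list on opposite sides. Rpl37 was at 43.6 FPKM with VD3 (28.7 to 58.5) and 153 with both agents, Ndufa5, a subunit of respiratory complex I, at 190.5 and 525, and Snrpe, of the spliceosome, at 404 and 944. Arl5c (11.3 and 52.1 FPKM), Fam71e1 (2.26 and 12.0), Mrps18c (94.95 and 381), Rps27rt (74.9 and 253) and Pet100 (50.6 and 130.3) were also higher. Gm21887, at 28.0 FPKM with VD3, was listed at 0 with both agents and was the 1 lower gene that the added rule named.

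Of 10717 genes, 89 were higher and 58 lower, and the median gene differed by 0.02. Unchanged genes of simulated pools gave 49 higher and 92 lower, 141 in all, which is about as many. Intervals in the simulation shrank with the drawn value, so it cannot set how many of these genes are chance calls. Of the genes counted in the deposited tables, 38 of the higher and 37 of the lower genes had under 100 counts in both pools. Among protein-coding genes of at least 100 counts, 28 were higher and 7 lower, against 11 and 47 in the simulation. The simulation thus gave more lower genes than the pools themselves. Single genes named here may still be chance calls. Ribosomal protein genes were at percentile 100 (median 0.45) and at 99.8 with matching on GC content and length. The matching may leave part of the length trend in this comparison too. Wnt-beta-catenin targets were at 1.6 (median -0.32), with Ccnd1 at 133 and 93.1 FPKM and Myc at 87.0 and 62.6, while Cdx1 was at 13.1 and 17.9, all with overlapping intervals. FGF-ERK feedback targets were at 3.7, primitive endoderm at 4.3, formative and primed pluripotency at 7.3, MLL-family complexes at 42.3 and HOX cluster genes at 80. By count, MLL-family complexes (median -0.25, against 0.01 by FPKM) and trophectoderm and trophoblast were at 1.3 and FGF-ERK feedback targets at 1.2, below the random lists; MLL-family complexes were at 19 by count with the matching. Psip1, of the MLL-family list, was at 123 and 285 FPKM with overlapping intervals. Fibroblast markers were at 8.0. Correlations across genes were -0.238 with GC content and -0.273 with length.

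The differences from untreated cells in both treated pools were related across genes. The correlation over 8965 protein-coding genes was 0.741 and the covariance 0.370, against 0.440 and 0.186 in simulated pools without any effect that share the untreated pool. Of 10652 genes in both comparisons, 253 were lower in both, against a mean of 10.8 and at most 17 in 100 simulations of unchanged pools that share the untreated pool. The simulated pools held no trend with GC content or length. Such a trend in the shared untreated pool would also raise the overlap and the correlation. The simulations therefore cannot tell it apart from a treatment. The 37 genes higher in both were within the simulated range, with a mean of 26.9 and at most 38. In the simulation, a low draw of the shared untreated pool shrinks its interval and can put a gene higher in both. This range therefore does not tell whether the 37 are chance calls. After adjustment for GC content and length, which covers protein-coding genes only and also centres their values, 62 were lower and 1 higher in both. Among protein-coding genes of at least 100 counts without adjustment, 174 were lower and 26 higher in both. Over all genes, 8 were higher in both with centred values and 11 with total count scaling. VD3 against untreated and VD3 plus MM-401 against VD3 share the VD3 pool and correlated at -0.301 (simulated -0.449), with a covariance of -0.106 (simulated -0.191). VD3 plus MM-401 against untreated and against VD3 correlated at 0.417 (simulated 0.604), with a covariance of 0.154 (simulated 0.287). Genes are not independent replicates in any of these correlations.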

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

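All tests in this part were chosen after the values were seen, except those of the trends across long non-coding RNAs. Assembled loci without a gene name were used in no comparison above. Among those with at least 5 FPKM and 100 counts, 6 of 254 were higher in the VD3 pool than in untreated cells, by the same criterion as for genes, and 68 of 304 were higher in the VD3 plus MM-401 pool. The numbers lower were 11 and 12.

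The differences from untreated cells followed GC content and transcript length. A bias of library preparation or sequencing would act on any RNA, and across 160 long non-coding RNAs the VD3 difference also followed GC content, with a Spearman correlation of 0.383 (bootstrap interval 0.235 to 0.512), and across 209 of them the VD3 plus MM-401 difference followed length, at -0.357 (-0.472 to -0.228). Both values are consistent with a technical bias, which a treatment that acts on RNAs by composition would share; the GC trend across long non-coding RNAs with VD3 plus MM-401 was weaker, at 0.117 (-0.0228 to 0.258). Depth is argued against, since it would act on genes with few counts, while across protein-coding genes of at least 1000 counts in both pools the VD3 difference followed GC content at 0.556 (0.539 to 0.573) and the VD3 plus MM-401 difference followed length at -0.589 (-0.606 to -0.574). The treatment cannot be told apart from the pool, with 1 pool per group. The adjusted differences of both treated pools from untreated had a Spearman correlation of 0.629, but share the untreated pool.

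Nanog is listed at 2 loci with the same coordinates. The main locus was at 111 FPKM in untreated cells, 141 with VD3 and 85.8 with VD3 plus MM-401, and the other at 5.69, 0.252 and 69.7, while the sum differed less. Across 451 gene names with 2 loci, the differences of the main and the other locus between the VD3 plus MM-401 and VD3 pools correlated at -0.268 (-0.350 to -0.186), consistent with reads of 1 gene being assigned to either locus in the authors' tables. No biological explanation was tested.

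FPKM and counts disagreed at some genes. In VD3 plus MM-401 against untreated, the 2 log2 differences lay at least 1 apart for 14.1% of the 220 protein-coding genes whose locus names a small RNA and for 1.85% of the 8599 others. That 7.62-fold ratio is consistent with short RNAs inside a locus setting its FPKM, as may be the case for Fgd6. No biological explanation was tested.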

How the results depend on the processing

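No paired analysis was possible because the tables hold 1 pooled column per group. For the same reason the planned count tests, the fit of fewer groups, the replicate block, the set tests on libraries and leaving out each library were not run. The alternatives called intervals, both scales, single loci, protein-coding, GC and length, and all those for lists and the correlation were chosen after seeing the data. The causes of the shifts below were not tested, except that a scaling moves all genes alike and a stricter filter leaves fewer.

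Genes higher with VD3 than untreated numbered 101, and 57 with a mean of at least 5 CPM, 46 centred on the median gene, 57 with total count scaling, 58 with median-of-ratios size factors, 386 without intervals, 52 for protein-coding genes of at least 100 counts and 14 adjusted for GC content and length. Those lower numbered 460, and 707 centred, 949 without intervals and 114 adjusted. All adjusted counts hold protein-coding genes only, and the adjustment also centres their values. Of such genes, 57 were higher and 343 lower with VD3 before it. With VD3 plus MM-401 these numbers were 294 and 189 against untreated, and 30 and 10 against VD3. The share of higher genes was 18.0%, and 6.11% centred, 8.6% with total counts, 8.8% with size factors, 10.9% adjusted, 11.2% at 5 CPM, 11.6% with intervals from the count table and 28.9% without intervals. For VD3 plus MM-401 against untreated, 467 higher became 189 centred, 201 with total counts, 247 with size factors, 1466 without intervals, 291 protein-coding and 52 adjusted; 294 lower became 684, 188 and 96 under the last 3. The share of higher genes was 61.4%, and 31.9% centred, 33.8% with total counts, 39.6% with size factors and 35.1% adjusted. For VD3 plus MM-401 against VD3, 89 higher became 44 at 5 CPM, 500 without intervals, 55 with intervals from the count table, 28 protein-coding and 16 adjusted, and 58 lower became 10, 216, 11, 7 and 10, and 97 at a minimum FPKM of 1 or with no filter beyond a count above 0. The share of 60.5% became 81.5% at 5 CPM, 83.3% with count intervals and 80% for protein-coding genes. Of the 10 lower protein-coding genes in this comparison, 2 were also 2-fold lower by count, and of the 30 higher ones 25 were also 2-fold higher. Small RNAs made up 29 of the 58 lower and 28 of the 89 higher genes.

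Genes higher in both treated pools than untreated numbered 37, and 8 centred, 11 with total counts, 11 with size factors, 181 without intervals and 1 adjusted; those lower in both numbered 253, and 578 without intervals and 62 adjusted. The Pearson correlation of 0.741 was 0.816 by counts and 0.662 adjusted. Kdm6a and Eda2r, lower with VD3, had adjusted differences of 0.15 and 0.01.

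Lists above the random lists with VD3 numbered 3, and 5 at a minimum mean of 5 FPKM; between the treated pools 1, and 2 by counts with GC and length matching. Lists below numbered 1 in each comparison. With VD3 this became 3 with the matching and 4 by counts with it, with VD3 plus MM-401 against untreated 4, 3 and, by counts alone, 2, and between the treated pools 0 with the matching, 3 by counts with it, 4 by counts alone and 0 at 5 FPKM. Other alternatives stayed within 1.5 times the main counts. By the limits used, 2.5% of random lists lie above and 2.5% below. Among 24 lists, a count of 1 on a side is by itself no more than chance can give. Members of a list that vary together would add to this. Few counts stand behind most small RNAs counted. With VD3 against untreated, 23 of 27 higher and 39 of 42 lower ones had under 100 counts in both pools.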

Other observations

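Gene families formed from gene symbols after seeing the data are given as values, and both differences from untreated cells share the untreated pool. The percentile of each family among random lists matched on expression, GC content and length is given to set it beside the trends with composition, and is no test, since the families were chosen for their values. Of 266 measured zinc finger genes of the Zfp series, many of which encode KRAB repressors, 213 lay below the median gene with VD3 and 212 with VD3 plus MM-401, with medians of -0.78 and -0.56 relative to it, both at percentile 0.0. By the 2-fold criterion with intervals apart, 43 of them were lower with VD3, and 30 were lower and 3 higher with VD3 plus MM-401. Genes of the structural maintenance of chromosomes family, which fold and hold chromosomes, had relative medians of -2.19 and -2.08 over 7 members, at percentiles 0.1 and 0.0, with 2 and 3 lower by that criterion. Smc2 was at 53.8, 10.2 and 10.5 FPKM, and Smc4 at 139.9, 32.0 and 23.7 FPKM, in the untreated, VD3 and VD3 plus MM-401 pools; the intervals of Smc4 overlapped between untreated and VD3.

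The Nduf symbol series names subunits of respiratory complex I and also assembly factors, which the set does not leave out. Of its 43 measured genes, 43 lay above the median gene in VD3 plus MM-401 against untreated cells. Their relative median was 0.97 at percentile 100, and 16 were higher by the criterion. Against VD3, 41 lay above the median gene, with a relative median of 0.58 at percentile 100, but 1 was higher by the criterion. The wide length bins of the matching may leave part of the length trend in these percentiles. Mitochondrial ribosomal protein genes had relative medians of 0.30 with VD3, 0.59 with VD3 plus MM-401 and 0.31 between the treated pools, at percentiles 100, 99.0 and 96.4, with 1, 14 and 1 of 73 higher by the criterion. The last lies within the random lists, and short transcripts as a class were higher in that comparison, with a median difference of 0.38 in the bin of the shortest. The Nduf genes with VD3 against untreated were at 73.6. Proteasome subunits were at 95.4 with VD3, 90.3 with VD3 plus MM-401 and 66.6 between the treated pools, and kinesins at 2.8, 4.6 and 67.6, all within the random lists.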
